A study of Homo sapiens with 6 samples.

How the data were processed

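The deposited file held read counts and FPKM (fragments per kilobase of transcript per 1e6 mapped reads) for 21996 genes with RefSeq transcripts in 6 libraries. The submitters' notes list FastQC 0.11.5, Trimmomatic 0.32, HISAT2, Bowtie2 and StringTie and the genome build hg19, without roles or settings. The read counts were whole numbers and entered the model as deposited. The FPKM values were made by the submitters and served as an alternative, as log2 of FPKM plus 1.

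The comparisons, the alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. Genes were kept by edgeR's filterByExpr with the culture state as the group, which left 16790 genes tested. Counts were scaled by TMM, and CPM (counts per 1e6 reads) are relative to the TMM-scaled library size. Culture state and form of collection entered 1 additive quasi-likelihood model in edgeR 4.0.16 (R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. Each of the 6 groups had 1 library, so the error of that model had 2 residual degrees of freedom and held any interaction of state with collection. A p from it, always two-sided, therefore tests the mean change over both collections, or over the 3 states. A change in 1 collection alone can still pass. For detached against attached cells, INO80B-WBP1 passed (edgeR adjusted p = 0.00893) with log2 ratios of −9.13 in single cells and −0.06 in clusters. The sign was the same in both collections for 5307 of the 5308 genes that passed there. It was the same for 64 of 64 for reattached against attached cells and 1909 of 1910 for reattached against detached cells. A comparison of 1 library with 1 library had no test. It was given as the log2 ratio of CPM with a prior count of 0.5 and a 95% exact conditional (Clopper-Pearson) interval. Intervals and floors cover counting error only, since the reads carry no molecular identifiers. The notes do not say whether 1 count stands for a read or a read pair, or how reads that map to several places were counted. If both reads of a pair were counted, the intervals are too narrow, and the read totals count each fragment again. Genes with at least 50 reads in the higher library entered the counts of 2-fold ratios.

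Lists were tested with camera in limma 3.58.1, with a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a comparison. The median log2 ratio of each list in a pair of libraries was ranked among 10000 random lists of the same size matched on mean expression. These were not matched on transcript length or GC content. The list of 13 mitochondrially encoded protein genes had 0 genes in the file under either of their symbols, while the mitochondrial ribosomal RNA genes RNR1 and RNR2 were present.

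The rule for named genes took, in each direction, the 10 largest changes among genes past the threshold with the same sign in every pair of libraries. Free places went to genes not past the threshold, ranked by the interval bound nearest 0 of their weakest pair. In a pair of libraries it took the 10 genes in each direction with the interval bound farthest from 0. That rule named mostly genes with 0 reads in 1 group, so a second rule was chosen after the data were seen. It took 15 genes in each direction with a mean of at least 50 CPM, or, for a pair, at least 1000 reads in the higher library and 50 in the lower, without readthrough genes. Members of lists are given as examples by the size of their change. A fold against a group without reads was computed against a floor of 3 counts over the group.

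The alternatives were DESeq2 size factors, library size alone, other filters, the DESeq2 1.42.0 Wald test, limma-voom, limma on log2 FPKM, no covariate, another prior count or minimum of reads, and each library left out in turn. A fit with 1 library left out keeps 1 library of that state. The error of such a fit comes from the pairs of the other states alone. Counts of genes that pass can therefore change although their fold changes do not. For comparisons with the state left with 1 library, the p of such a fit no longer tests the mean change over both collections. Removal of each library's trend with transcript length and GC content was added after the data were seen. Length and GC content were matched for 95.8% of the genes tested. The steps were run on simulated data in which 100 genes per size were changed. At a log2 change of 2, 61% to 72% of the genes passed. At a log2 change of 1, 1% to 6% passed. False calls were 3.12% of the calls for reattached against attached cells and 9.30% for clusters against single cells. They were 15.9% for detached against attached cells and 18.3% for reattached against detached cells. Only the first of these shares lay within the rate set by the threshold. The number of changed genes was the same for each comparison, unlike the counts that passed in the real data. The shares that passed and the false shares may therefore not carry over to the real comparisons.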

Results

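RNA sequencing was done on MCF7 cells, a human breast cancer line that carries the oestrogen receptor, in 3 culture states and 2 forms of collection. Attached cells (ATT) grew on a plate, detached cells (DE) grew in suspension, and reattached cells (RE) were put back on a regular plate to mimic disseminated cells. Each state was collected as single cells (SC) and as clusters (CL). The 6 groups had 1 library each, so no value has a replicate. Poly(A) RNA was sequenced as stranded libraries. Total read counts were 64500886 in ATT-SC, 86834590 in ATT-CL, 73063757 in DE-SC, 72948840 in DE-CL, 90735543 in RE-SC and 87701745 in RE-CL. The number of genes with reads was 17513, 17886, 19464, 20090, 18706 and 18756 in the same order.

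The ATT-SC library stood apart from the 5 others in its label, which carries another letter, and in some of its reads. It lacked reads of KRT5, KRT14 and KRT6A, keratins of basal and squamous epithelium, which had 674 to 3359 reads in each of the other libraries. Genes with 0 reads in 1 library and at least 50 in each of the 5 others numbered 20 for ATT-SC, 4 for ATT-CL, 1 for DE-SC and 0 for the rest. RPL13A, a ribosomal protein gene with many pseudogenes, had 1493 CPM in ATT-SC and 53.4 to 86.0 CPM elsewhere. Over all genes, ATT-SC was not clearly the more distant of the attached libraries. For RE against ATT, 2176 genes differed 2-fold in clusters and 1762 in single cells. The SD of those log2 ratios went the other way, at 0.840 in clusters and 0.964 in single cells. Some counts of genes and of list members are therefore also given with 1 library left out. They show dependence on single libraries, either through the fold changes or through the error of the fit. A higher or lower count alone does not tell these apart, and other lists may have moved as much.

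**Figure D1:**
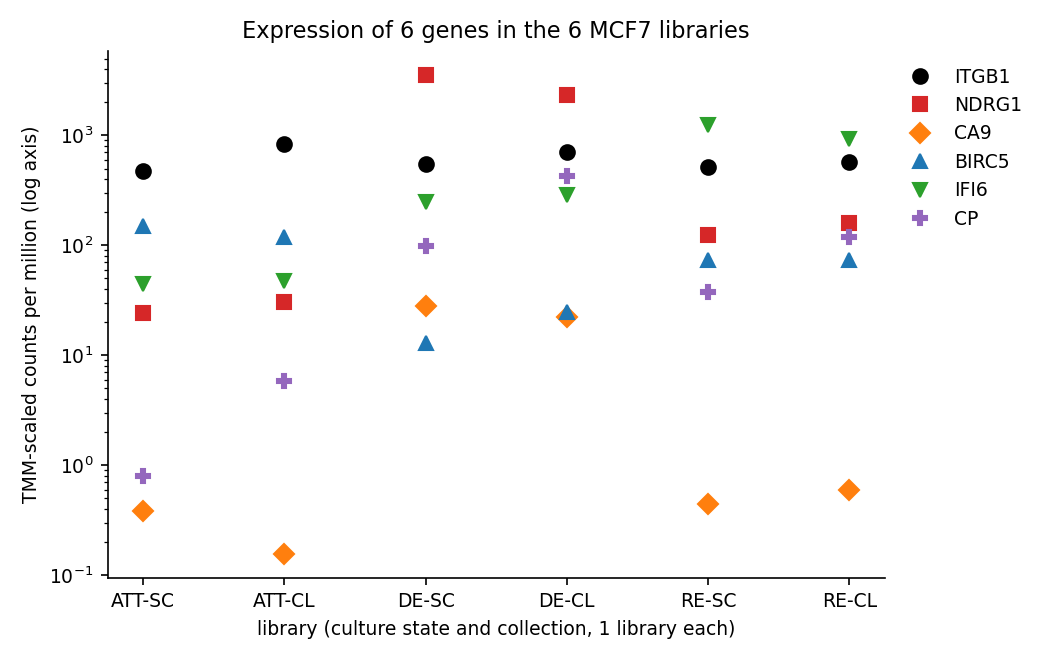
CPM of ITGB1, NDRG1, CA9, BIRC5, IFI6 and CP, on a log axis, in each of the 6 libraries, 1 point per library and no error bar because each group had 1 library. NDRG1 sits at 24.4 and 30.6 CPM in the attached libraries and at 3566 and 2319 CPM in the detached ones.

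ITGB1, the integrin subunit named in the series' title (gene 3688), was measured in every library with 29986 to 64329 reads. Its level was 478 CPM in ATT-SC, 839 in ATT-CL, 547 in DE-SC, 711 in DE-CL, 520 in RE-SC and 577 in RE-CL. It was higher in clusters than in single cells in 3 of 3 states. The log2 ratio was 0.81 (95% interval 0.79 to 0.83) in attached cells, 0.38 (0.36 to 0.40) in detached cells and 0.15 (0.13 to 0.17) in reattached cells. Over the 3 states, the log2 fold change of 0.45 ± 0.21 (SE) did not pass the threshold (adjusted p = 0.892, unadjusted p = 0.0668). Without either attached library it was 0.27, and with the trend of length and GC content removed 0.21. It was 0.48 without DE-SC, 0.47 without DE-CL and 0.59 without either reattached library. Between states, ITGB1 did not pass either. The log2 fold change was −0.03 ± 0.25 for DE against ATT (adjusted p = 0.930), −0.21 ± 0.25 for RE against ATT (adjusted p = 0.833) and −0.18 ± 0.25 for RE against DE (adjusted p = 0.662). Its sign for DE against ATT turned with library size alone, with FPKM and without ATT-CL (0.15, 0.16 and 0.25). Activation of the integrin protein is not measured by RNA counts.

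The comparison of detached with attached cells asks what growth in suspension changes. In suspension, hypoxia genes rose and genes of cell division fell. NDRG1, a gene induced by low oxygen, rose 107-fold, from 24.4 and 30.6 CPM in ATT-SC and ATT-CL to 3566 and 2319 CPM in DE-SC and DE-CL. Of 24 hypoxia genes, 22 rose and 0 fell, and adjusted over the list alone 23 rose. Among them, CA9, a carbonic anhydrase, rose by 6.59 ± 0.51 (log2 ± SE) and LOX, a collagen cross-linking enzyme, by 7.50 ± 0.67. Of 25 genes of G2/M and mitosis, 24 fell (25 adjusted over the list alone), with BIRC5 (survivin) at −2.87 ± 0.37 and CCNB1 (cyclin B1) at −2.60 ± 0.29. Of 25 genes of DNA replication and S phase, 23 fell (24 adjusted over the list alone), with GINS2 at −3.03 ± 0.30 and CDC45 at −2.83 ± 0.39, both parts of the replicative helicase. Without ATT-SC, 22 hypoxia genes rose and all 25 genes of each of the cell cycle lists fell. Without DE-SC 13 S phase genes fell.

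Of 27 interferon-stimulated genes, 25 rose and 1 fell, with the same counts adjusted over the list alone. RSAD2 (viperin) changed by 4.03 ± 0.71 and OAS2 by 3.96 ± 0.68. Of 22 NF-kB and inflammatory genes, 12 rose (13 rose and 1 fell adjusted over the list alone), among them the chemokine gene CXCL8 at 2.85 ± 0.40 and the adhesion receptor gene ICAM1 at 2.76 ± 0.30. Of 25 immediate early genes, 16 rose and 1 fell (18 and 1 adjusted over the list alone), with NR4A1 at 3.34 ± 0.29. Without DE-SC 4 NF-kB genes rose.

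Of 14 integrin genes, 6 rose and 0 fell (7 adjusted over the list alone), and 8 rose without ATT-SC. ITGA5, the alpha subunit that pairs with ITGB1 as a fibronectin receptor, rose by 3.60 ± 0.28 (adjusted p = 0.00249), from 36.6 and 32.6 CPM to 481 and 363 CPM. ITGB7, ITGB6 and ITGA2 rose by 2.63 ± 0.43, 1.89 ± 0.30 and 1.49 ± 0.29. Of 23 genes of extracellular matrix and basement membrane, 14 rose and 1 fell, with the same counts adjusted over the list alone. FN1 (fibronectin) rose by 2.78 ± 0.35, and COL12A1 fell by 3.01 ± 0.77. Of 20 mesenchymal and EMT genes, 12 rose and 0 fell, also adjusted over the list alone, with LOXL2 at 3.80 ± 0.43. Of 14 stem cell associated genes, 7 rose and 1 fell, also adjusted over the list alone, with SOX9 at 4.04 ± 0.30 and KLF4 at 2.78 ± 0.27. Without DE-CL 2 integrins and 9 matrix genes rose, and without ATT-CL 4 matrix genes fell. In 25 genes of integrin signalling and focal adhesion, 2 rose and 3 fell, and 0 passed adjusted over the list alone. Their counts were 10 and 3 without ATT-SC, 3 and 8 without ATT-CL, 0 and 0 without DE-SC or DE-CL, and 1 and 2 without RE-SC or RE-CL.

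Of 19 glycolysis genes, 9 rose and 0 fell (10 and 1 adjusted over the list alone), with ENO2 at 4.17 ± 0.33 and HK2 at 3.66 ± 0.36. Of 26 nuclear genes of oxidative phosphorylation, 19 fell (21 adjusted over the list alone), with ATP5B, an ATP synthase subunit, at −1.60 ± 0.22. Of 28 cytoplasmic ribosomal protein genes, 14 fell (22 adjusted over the list alone), with RPS2 at −1.36 ± 0.21. Of 25 oestrogen receptor targets, 8 fell (2 rose and 11 fell adjusted over the list alone), with PDZK1 at −4.09 ± 0.38 and CXCL12 at −2.92 ± 0.46. Of 19 FOXO targets and PI3K feedback genes, 10 rose (13 adjusted over the list alone). Of 22 p53 targets, 11 rose and 1 fell, with the same counts adjusted over the list alone. Of 22 lysosome and autophagy genes, 12 rose and 2 fell (14 and 2 adjusted over the list alone). Of 24 genes of cholesterol synthesis, 1 rose and 7 fell, also adjusted over the list alone. Without ATT-SC 27 ribosomal protein genes fell, 17 FOXO targets and 3 oestrogen receptor targets rose, and 5 cholesterol genes rose while 9 fell. Without ATT-CL 4 oestrogen receptor targets rose and 12 cholesterol genes fell. Without DE-SC 5 glycolysis genes, 7 p53 targets and 5 lysosome genes rose, and 7 genes of oxidative phosphorylation, 5 oestrogen receptor targets and 3 cholesterol genes fell. Without DE-CL 2 genes of oxidative phosphorylation, 1 ribosomal protein gene and 4 cholesterol genes fell.

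Some markers of other cell types passed as well. Of 12 basal breast and myoepithelial markers, 6 rose and 1 fell, also adjusted over the list alone, where KRT5 and KRT14 had 0 reads in ATT-SC. Of 7 blood and immune markers, 4 rose, also adjusted over the list alone, with CD68, a lysosomal protein gene of macrophages, at 3.49 ± 0.36. Of 8 fibroblast markers, 2 rose, and of 6 endothelial markers, 1 rose, both also adjusted over the list alone. Of 8 nuclear long RNAs, 4 rose (5 adjusted over the list alone). In the lists not named so far, members rose and fell in apoptosis (6 and 2 of 21), YAP and TEAD targets (6 and 1 of 21), epithelial junctions and keratins (4 and 2 of 27), heat shock (3 and 5 of 17) and NRF2 targets (1 and 5 of 21), each with the same counts adjusted over the list alone. Members also rose and fell in fatty acid synthesis (3 and 1 of 16), the unfolded protein response (7 and 0 of 20), the ATF4 response (6 and 5 of 24) and histones (6 and 0 of 16). Adjusted over the list alone, these counts were 2 and 1, 8 and 1, 8 and 6, and 7 and 0. The counts that rose and fell changed when single libraries were left out, through the fold changes, the error or both. Without ATT-SC they were 2 and 10 for NRF2 targets, 3 and 11 for heat shock, 11 and 1 for YAP and TEAD targets, 10 and 2 for epithelial junctions and keratins, 8 and 6 for the unfolded protein response, 5 and 4 for fatty acid synthesis, and 4 and 0 for fibroblast markers. Without ATT-CL they were 10 and 6 for NRF2 targets, 7 and 4 for epithelial junctions, 6 and 4 for YAP and TEAD targets, 10 and 3 for apoptosis, 11 and 7 for the ATF4 response, 4 and 5 for fatty acid synthesis, 10 and 1 for basal markers, and 4 and 0 for endothelial markers. Without DE-SC they were 0 and 4 for NRF2 targets, 2 and 1 for apoptosis, 3 and 2 for the ATF4 response, 3 and 0 for the unfolded protein response and 2 and 0 for blood markers. Without DE-CL they were 5 and 2 for NRF2 targets, 2 and 0 for apoptosis, 2 and 2 for heat shock, 1 and 2 for epithelial junctions and 10 and 0 for basal markers. By camera, 21 of the 33 lists passed with the preset correlation, and 0 passed with an estimated correlation (lowest adjusted p = 0.480 with an estimated correlation).

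Beyond the lists, abundant genes that rose included CEMIP, a hyaluronan-binding protein gene (106-fold), CEACAM5, the carcinoembryonic antigen gene (69.9-fold), the mucin gene MUC5B (27.4-fold), the water channel gene AQP3 (21.2-fold) and the lipid droplet gene PLIN2 (18.6-fold). Abundant genes that fell included STMN1, a microtubule regulator (7.41-fold), and GLA, a lysosomal galactosidase (7.22-fold). The 20 genes with the largest fitted changes each had 0 reads in 1 of the states. TREM1 was at least 535-fold higher in DE, COL20A1 at least 427-fold higher and SPIN2A, which has a near copy, SPIN2B, at least 181-fold lower. C4A was at least 469-fold higher, but it has a near copy, C4B, so its level is uncertain. In all, 5308 of 16790 genes passed, of which 2786 rose and 2522 fell, and 4758 changed at least 2-fold. Across genes, the ratios in single cells and in clusters correlated (Pearson 0.680), and 76.8% had the same sign. Without either attached library more genes passed, and without either detached library fewer did. In each of these fits 1 state rested on 1 library. With library size alone, the median of all genes moved from 0.05 to 0.23 (log2) and the share of passing genes that rose from 52.5% to 63.5%. With the trend of length and GC content removed the share was 45.9% (3023 rose and 3566 fell).

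**Figure D2:**
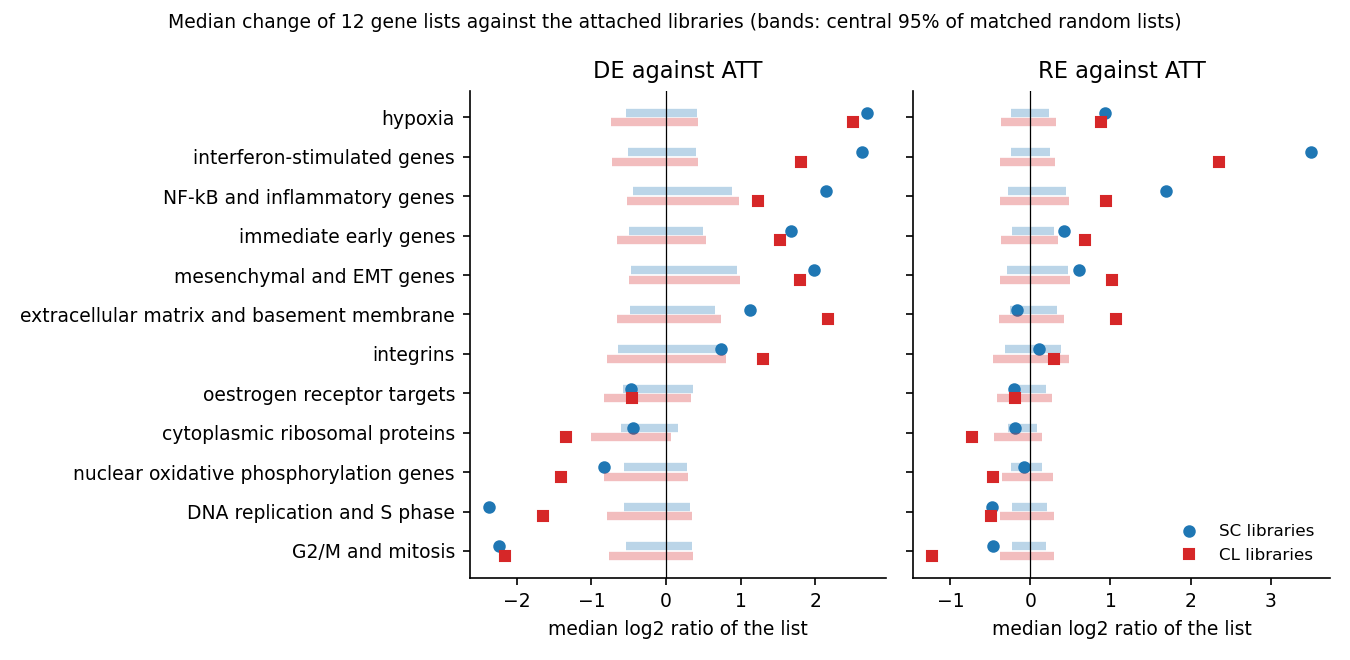
Median log2 ratio of 12 gene lists for DE against ATT (left) and RE against ATT (right), with blue circles for the single-cell libraries, red squares for the cluster libraries and pale bands for the central 95% of matched random lists. The hypoxia median is 2.69 in single cells and 2.51 in clusters for DE against ATT, and the interferon median is 3.50 and 2.36 for RE against ATT.

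The comparison of reattached with attached cells asks what remains different once cells are back on a plate. Of 27 interferon-stimulated genes, 12 rose and 0 fell over all genes tested, and adjusted over the list alone 26 rose. IFI6 rose 23.6-fold, from 44.2 and 47.1 CPM in ATT-SC and ATT-CL to 1239 and 922 CPM in RE-SC and RE-CL, and by 4.56 ± 0.30 on the log2 scale (adjusted p = 0.0105). IFI27 rose by 5.11 ± 0.42 and IFI44L by 6.76 ± 0.92. The list's median log2 fold change was 2.86, and 20 to 26 members rose when any 1 library was left out. Of 22 NF-kB and inflammatory genes, 2 rose (11 adjusted over the list alone), CXCL8 by 3.37 ± 0.41 and ICAM1 by 2.17 ± 0.30. Without ATT-SC 8 of them rose, without ATT-CL 13, and without either detached library 5.

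Single members of other lists also rose. NDRG1 was the 1 hypoxia gene of 24 that rose (9 adjusted over the list alone), by 2.37 ± 0.31. SOX9 rose by 2.58 ± 0.29 as the 1 stem cell associated gene of 14 (4 adjusted over the list alone). LAMA3, a laminin chain gene, rose by 1.97 ± 0.26 as the 1 matrix gene of 23 (4 adjusted over the list alone). Without ATT-SC 12 hypoxia genes rose and 1 fell, and 6 stem cell associated and 11 matrix genes rose. Without ATT-CL 12 hypoxia genes rose, 5 stem cell associated genes rose and 1 fell, and 5 matrix genes rose and 5 fell. The matrix list's median was 1.00 without ATT-SC and −0.06 without ATT-CL. Without DE-SC, DE-CL, RE-SC and RE-CL in turn, 5, 5, 5 and 3 hypoxia genes, 3, 3, 1 and 2 stem cell associated genes and 3, 3, 0 and 3 matrix genes rose. Among abundant genes, CP (ceruloplasmin) rose 29.7-fold, CYP1A1, a cytochrome P450 gene, 14.0-fold, and CEACAM5 10.7-fold. MIR34AHG, the host gene of a p53-induced microRNA, rose by 7.04 ± 0.42. The 3 genes that fell were LINC00052 by 2.45 ± 0.34, SPIN2A, which was at least 217-fold lower, and FAM47E-STBD1, a readthrough gene whose level is uncertain.

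The G2/M list had a median log2 fold change of −0.79 with 0 of 25 members past the threshold, also adjusted over the list alone. Without ATT-SC 15 of its members fell, and without ATT-CL 6 fell. Integrins had 0 of 14 members past the threshold, also adjusted over the list alone. Without ATT-SC 17 ribosomal protein genes fell and 11 FOXO targets rose, and without ATT-CL 11 S phase genes fell and 11 NRF2 targets rose, where 0 of each passed with all libraries. By camera, 19 of the 33 lists passed with the preset correlation, among them those of fibroblast, blood and immune, and basal markers, none of whose members passed over all genes tested (adjusted over the list alone, 3 blood and immune markers rose and 1 basal marker fell). None passed with an estimated correlation (lowest adjusted p = 0.432 with an estimated correlation). Without ATT-SC 5 fibroblast and 3 blood and immune markers rose, and 1 basal marker rose and 1 fell. Without ATT-CL 7 basal markers rose and 1 fell, and without either detached library 5 rose. COL1A2 and KRT5, members of the fibroblast and basal lists, had 0 reads in ATT-SC. In all, 64 genes passed, of which 61 rose and 3 fell, and 1690 had an unadjusted p under 0.05. The ratios in single cells and in clusters correlated weakly across genes (Pearson 0.215), and 49.98% had the same sign. Without either attached library more genes passed, which included the 64, but attached cells then rested on 1 library. Without any 1 of the 4 other libraries 139 to 340 passed, and the DESeq2 Wald test gave 435.

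The comparison of reattached with detached cells asks which changes of suspension turn back on a plate. Of 24 hypoxia genes, 19 fell (23 adjusted over the list alone), with CA9 at −5.57 ± 0.47 and NDRG1 at −4.37 ± 0.34. Of 25 G2/M genes, 14 rose (21 adjusted over the list alone), with BIRC5 at 1.99 ± 0.36 and CCNB1 at 1.83 ± 0.28. Of 25 S phase genes, 14 rose (23 adjusted over the list alone), with GINS2 at 2.10 ± 0.29. Without either attached library 23 hypoxia genes fell and 24 genes of each cell cycle list rose. Without DE-SC, DE-CL, RE-SC and RE-CL in turn, 11, 14, 10 and 15 hypoxia genes fell, and 0, 9, 2 and 21 G2/M genes and 0, 11, 2 and 8 S phase genes rose.

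Of 14 integrin genes, 5 fell (6 adjusted over the list alone), with ITGA5 at −2.74 ± 0.27 (adjusted p = 0.0124). Of 20 mesenchymal and EMT genes, 7 fell (10 adjusted over the list alone), and of 23 matrix genes, 8 fell (9 adjusted over the list alone), with FN1 at −1.92 ± 0.34. Of 19 glycolysis genes, 9 fell (1 rose and 10 fell adjusted over the list alone), with ENO2 at −3.28 ± 0.32. Of 25 immediate early genes, 10 fell (2 rose and 14 fell adjusted over the list alone), and of 19 FOXO targets and PI3K feedback genes, 7 fell (10 adjusted over the list alone). Genes of oxidative phosphorylation rose in 6 of 26 (16 adjusted over the list alone). Oestrogen receptor targets rose in 4 of 25 (8 rose and 1 fell adjusted over the list alone), with PDZK1 at 3.66 ± 0.38. NRF2 targets rose in 5 of 21 (7 adjusted over the list alone), with NQO1, a quinone reductase, at 2.31 ± 0.24. Interferon-stimulated genes rose further in 7 of 27 (11 adjusted over the list alone), with IFI44L at 3.01 ± 0.71 and IFI6 at 2.01 ± 0.27. Without ATT-SC 8 integrins, 13 mesenchymal, 13 matrix, 19 immediate early and 16 FOXO genes fell, and 23 genes of oxidative phosphorylation, 14 oestrogen receptor targets, 11 NRF2 targets and 17 interferon-stimulated genes rose, with the same counts without ATT-CL. Without DE-SC, DE-CL, RE-SC and RE-CL in turn, 3, 5, 2 and 6 mesenchymal, 5, 3, 0 and 7 matrix, 5, 9, 3 and 8 glycolysis, 6, 4, 5 and 6 immediate early and 4, 2, 2 and 4 FOXO genes fell. In the same order, 5, 2, 2 and 3 NRF2 targets and 6, 4, 0 and 5 interferon-stimulated genes rose. Without any 1 of these 4 libraries 1 integrin fell and 0 genes of oxidative phosphorylation rose.

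Of 12 basal markers, 3 fell (5 adjusted over the list alone). Of 7 blood and immune markers 2 fell, of 6 endothelial markers 1 fell, and of 8 nuclear long RNAs 4 fell, each also adjusted over the list alone, and 0 of 8 fibroblast markers passed. Without either attached library 1 basal marker rose and 6 fell, and 1 endothelial marker rose and 1 fell. Without DE-SC 2 basal markers rose and 1 fell, and without RE-SC 0 endothelial markers passed. Without any 1 of the detached or reattached libraries 1 blood and immune marker fell. MUC5B fell 16.5-fold and CEMIP 15.4-fold from their levels in suspension. SHH, a signalling ligand, rose by 4.05 ± 0.58 and AOX1, an aldehyde oxidase, by 3.97 ± 0.51. In all, 1910 genes passed, of which 857 rose and 1053 fell. With the trend of length and GC content removed the balance turned, with 1954 that rose and 1542 that fell. By camera, 19 of the 33 lists passed with the preset correlation and 0 with an estimated correlation (lowest adjusted p = 0.553 with an estimated correlation). Without either attached library more genes passed, and more rose than fell, although neither library enters this difference. Both enter its error, which then came from the detached and reattached pairs alone. The SD of the log2 ratios of clusters to single cells was 0.507 and 0.394 in those pairs and 0.991 in attached cells. Without DE-SC, DE-CL, RE-SC or RE-CL the count was 573, 636, 309 and 1048, of which 116, 235, 75 and 426 rose.

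The comparison of clusters with single cells asks what collection as clusters changes. Across the 3 states, 0 of 16790 genes passed the threshold, CP among them. CP was higher in clusters in 3 of 3 states, with log2 ratios of 2.87 (95% interval 2.46 to 3.33) in attached, 2.11 (2.07 to 2.15) in detached and 1.66 (1.61 to 1.72) in reattached cells. ALDH1A3, an aldehyde dehydrogenase gene used as a stem cell marker, was higher by 2.01, 1.97 and 1.27, and CXCL8 by 2.33, 1.42 and 1.71. The smallest adjusted p was 0.892 in edgeR, with 439 genes at an unadjusted p under 0.05. The DESeq2 Wald test gave 19 genes, limma-voom 0 and limma on log2 FPKM 0. Leaving out any 1 library gave 8 to 33. By camera, 12 of the 33 lists passed with the preset correlation, with G2/M, NRF2, NF-kB, mesenchymal, ribosomal, fibroblast and endothelial genes higher in clusters and cholesterol synthesis, fatty acid synthesis, glycolysis, immediate early and FOXO genes lower. None passed with an estimated correlation (lowest adjusted p = 0.728 with an estimated correlation). The medians of fibroblast and endothelial markers were the farthest from 0, at 1.51 and 1.15, and were 1.06 and 0.69 without ATT-SC or ATT-CL. Their members had low counts. The 6 endothelial markers together summed to between 1.13 CPM in ATT-SC and 9.74 CPM in DE-CL. In attached cells the summed level of the fibroblast markers was lower in clusters (20.02 against 49.98 CPM), while in detached and reattached cells it was higher (53.02 against 39.1 and 51.0 against 30.6). Without either attached library, the median went from 0.36 to 0.07 for NRF2 targets and from 0.21 to 0.07 for NF-kB genes. It went from −0.42 to −0.06 for FOXO genes and from 0.25 to −0.01 for ribosomal proteins. It went from 0.37 to 0.28 for G2/M genes without ATT-SC, to 0.23 without DE-SC and to 0.58 without RE-SC.

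In attached cells, 3156 of 13720 genes with at least 50 reads differed 2-fold or more between clusters and single cells (SD of the log2 ratios 0.991). NRF2 targets (median 1.09, 20 of 21 higher), interferon-stimulated genes (0.82, 20 of 27), ribosomal proteins (0.75, 26 of 28), NF-kB genes (0.72, 19 of 22) and G2/M genes (0.58, 18 of 25) were higher in ATT-CL than in ATT-SC. Matrix genes (−0.85, 18 of 23 lower), FOXO targets (−0.90, 16 of 19) and YAP and TEAD targets (−0.76, 16 of 21) were lower. Each of these medians lay outside the central 95% of random lists, which were matched on mean expression only. In this pair the log2 ratio correlated with GC content (Spearman −0.504). A trend with transcript length and GC content fitted 32.8% of its variance, against 9.36% in detached and 2.47% in reattached cells. How far the list medians follow that trend was not tested. BIRC3, an inhibitor of apoptosis, was 16.2-fold higher in ATT-CL, and S100A8 and S100A9, calcium-binding proteins of inflammation, were 12.2-fold and 11.6-fold higher. SCD, a fatty acid desaturase, was 5.73-fold lower. Basal markers had a median of 1.56, with 5 of 12 members at 0 reads in ATT-SC. Fibroblast markers had a median of 2.52 (5 of 8 higher), with 3 members at 0 reads in 1 of the libraries and 2 others too low to rank. Their summed level ran the other way, from 49.98 CPM in ATT-SC to 20.02 CPM in ATT-CL, because COL3A1, the member with the most reads, went from 39.1 to 12.1 CPM. Endothelial markers had a median of 2.22 (5 of 6 higher), or 1.62 with genes at 0 reads set to their bound. KRT6A was at least 341-fold higher in ATT-CL, and 5 of the 20 genes with the widest ratios were readthrough genes, whose levels are uncertain. With the trend of length and GC content removed, 1704 genes differed 2-fold, and with FPKM 1464 did.

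In detached cells, 610 of 14368 genes differed 2-fold or more (SD 0.507). Genes of division were higher in clusters, with G2/M at a median of 0.79 and 25 of 25 members higher, and S phase at 0.54 and 23 of 25. Integrins had a median of 0.52, with 11 of 14 higher. Fibroblast markers had a median of 1.19 with 8 of 8 higher, and endothelial markers, with a median of 0.80 and 6 of 6 higher, lay within the range of random lists. Basal markers had a median of −0.57 with 9 of 12 lower. Genes of the unfolded protein response were lower, with a median of −0.46 and 20 of 20 lower, as were p53 targets (−0.42, 18 of 22 lower), hypoxia genes (−0.33, 19 of 24) and histones (−0.64, 14 of 16). STOM, a membrane protein gene, was 5.84-fold lower in DE-CL than in DE-SC. With a minimum of 10 reads 1205 genes differed 2-fold, and with FPKM 112 did.

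In reattached cells, 262 of 14108 genes differed 2-fold or more (SD 0.394). Matrix genes were higher in clusters, with a median of 0.46 and 23 of 23 higher, as were mesenchymal genes (0.41, 17 of 20), fibroblast markers (0.80, 8 of 8), NRF2 targets (0.25, 18 of 21) and ribosomal proteins (0.15, 28 of 28). Endothelial markers (0.59, 4 of 6 higher) lay within the range of random lists, and basal markers were lower (−0.46, 9 of 12). Interferon-stimulated genes were lower (−0.28, 24 of 27), as were oestrogen receptor targets (−0.24, 20 of 25) and G2/M genes (−0.19, 25 of 25). IGFBP3, a binding protein of insulin-like growth factors, was 15.1-fold higher in RE-CL, and the transcription factor genes CEBPB and CEBPA were 10.1-fold and 6.50-fold higher. The nuclear RNA MALAT1 was 4.56-fold lower. With a minimum of 10 reads 887 genes differed 2-fold, and with FPKM 56 did. Across genes, the cluster ratios of the 3 states hardly correlated, at 0.096 for ATT with DE, −0.021 for ATT with RE and 0.066 for DE with RE (Pearson).

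**Figure D3:**
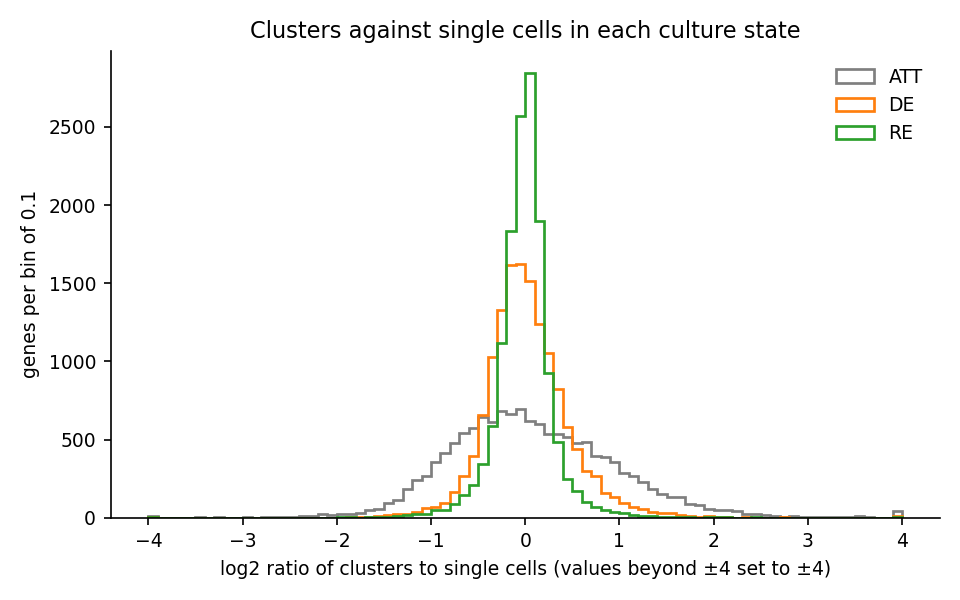
Number of genes, in bins of 0.1, by log2 ratio of clusters to single cells, for genes with at least 50 reads in the higher library of each culture state, with values beyond ±4 set to ±4. The SD is 0.991 in attached, 0.507 in detached and 0.394 in reattached cells.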

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

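The tests of the reads missing from ATT-SC, of the spread between the attached libraries and of readthrough genes were chosen after these results were seen.

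Of 43 squamous marker genes, keratins among them, chosen after the missing genes were seen, 29 had 0 reads in ATT-SC against 0 to 2 elsewhere, and 10 had at least 10 reads in ATT-SC against 38 to 42 elsewhere. Lower depth is argued against, since at least 73.5 reads were expected in ATT-SC for each of the 20 missing genes. These genes were chosen for at least 50 reads in each other library, so that number follows from the choice and from the depth of ATT-SC. Induction by suspension or by clusters cannot be told apart from a difference of ATT-SC alone, because ATT-SC was the 1 group with neither, although the 43 markers had medians of at least 161 reads in ATT-CL, DE-SC and RE-SC. Reads of squamous epithelium or another tissue shared by the 5 libraries could account for the pattern, with KRT14 at 14.0 to 35.4 CPM there. This cannot be told apart from other differences of ATT-SC, because the correlation of markers outside the pattern separates nothing. These 27 markers correlated with ATT-CL in every library, at 0.925 or more in the 4 others and at 0.864 in ATT-SC. Their levels did differ, with at least 10 reads for 10 of the 27 in ATT-SC and for 23 to 26 in the 4 others. Not every marker was low in ATT-SC. TP63 had 177 reads in ATT-SC and 40 to 170 in the other libraries, and KRT15 had 724 and 621 to 1174.

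ATT-CL and ATT-SC differed more than clusters and single cells did in the other states, with an SD of the log2 ratios of 0.991 against 0.507 and 0.394. Transcript length and GC content as the whole cause are argued against, since the SD stayed 1.71 times the larger of the others once the trend was removed. Counting error is argued against, since among genes with at least 1000 reads the SD was 2.20 times the larger of the others. ATT-SC as a library of another batch cannot be told apart from an effect of clusters in attached cells, because each group had 1 library. The same holds for ATT-CL as the library that differs. The trend with length and GC content lay more with ATT-CL. It fitted 26.2% of the variance of RE against ATT in clusters and 4.27% in single cells. For DE against ATT it fitted 19.3% in clusters and 2.76% in single cells. The SD of RE against ATT in single cells was 1.15 times that in clusters. Among genes with at least 1000 reads in both libraries the order turned, at 0.504 in single cells and 0.624 in clusters. A biological difference between attached clusters and attached single cells stays open, as untested.

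Readthrough genes, which span a pair of neighbouring genes, made up 14 of the 55 distinct genes named for the widest ratios of clusters to single cells (25.5%) and 0.756% of the genes tested. When the reads of each readthrough gene and of the genes it joins were summed, the median absolute log2 ratio was 0.191 instead of 8.15 over 15 ratios at 12 loci, with 0.490 at most. The readthrough reads were a median of 5.57% and at most 28.9% of each sum, so the sums would hardly move in any case. Reads moved between overlapping genes by the counting therefore cannot be told apart from a change of the readthrough RNA itself, which stays open, as untested.

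Some results went opposite ways in different pairs of libraries, and each such difference was not tested. For the ratio of clusters to single cells, the list medians in detached minus attached cells differed by 1.103 for matrix genes (from −0.85 to 0.25), −1.095 for interferon-stimulated genes (from 0.82 to −0.28), −0.97 for ribosomal proteins (from 0.75 to −0.22) and −2.13 for basal markers (from 1.56 to −0.57). In reattached minus attached cells they differed by 1.31 for matrix genes, −0.77 for G2/M genes, −1.09 for interferon-stimulated genes and −2.02 for basal markers. In reattached minus detached cells they differed by −0.98 for G2/M genes, 0.46 for hypoxia genes and 0.37 for ribosomal proteins.

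The same held for single genes, where the difference was not tested either. In detached minus attached cells, the log2 ratio of clusters to single cells differed by 5.44 for KTI12, 2.55 for MTPN, −2.59 for BOLA2, −10.47 for KRT76 and −10.27 for FDCSP, and the last 2 of these had 0 reads in ATT-SC, so that their values depend on the prior count. In reattached minus attached cells it differed by 4.68 for ARPP19, 3.93 for MED29, 3.85 for GNG4, 3.54 for IGFBP5, −2.27 for ZDHHC23, −2.73 for RRM2B, −4.43 for S100A7 and −10.81 for FDCSP. In reattached minus detached cells it differed by −4.40 for ZNF337. For ITGB1, the ratio of detached to attached cells was 0.43 lower in clusters than in single cells (−0.24 against 0.20, a difference of −0.43), and that of reattached to attached cells differed by −0.66 (−0.54 against 0.12).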

How the results depend on the processing

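The alternative that removes the trend with length and GC content was chosen after the data were seen, and all other alternatives were planned. Where a value moved, the cause was not tested. The depth allows intervals of about 0.02 (log2) on either side for ITGB1, so depth is not the limit there, while the single library per group is.

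Leaving out 1 library gave 2252 to 9087 genes for DE against ATT, 139 to 2683 for RE against ATT, 309 to 7559 for RE against DE and 8 to 33 for clusters against single cells. The DESeq2 Wald test gave 435 genes for RE against ATT, 3489 for RE against DE and 19 for clusters. FPKM gave 101 and 3071 for RE against ATT and RE against DE, the length and GC trend 104 and 3496, and library size alone 164 for RE against ATT. With an estimated correlation, 0 lists passed in each of DE against ATT, RE against ATT, RE against DE and clusters against single cells.

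With FPKM, genes that differed 2-fold numbered 1464, 112 and 56 for clusters in ATT, DE and RE, 3193 and 4003 for DE against ATT in single cells and clusters, 650 and 843 for RE against ATT, and 2279 and 1582 for RE against DE. A minimum of 10 reads gave 1205 for clusters in DE, 887 in RE and 2709 for RE against ATT in single cells. The length and GC trend gave 1704 for clusters in ATT and 1347 for RE against ATT in clusters. The correlation of RE against DE between collections was 0.826 with at least 50 reads and 0.864 with FPKM. With FPKM the cluster ratios correlated at 0.230 for ATT with DE and −0.123 for ATT with RE.

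The ITGB1 log2 fold change for DE against ATT turned to 0.153 with library size alone, 0.0121 with at least 50 reads, 0.157 with FPKM and 0.181 without the length and GC trend, and ran from −0.295 to 0.253 with 1 library left out. It ran from −0.482 to 0.0661 for RE against ATT and from −0.414 to 0.00886 for RE against DE. Within clusters, DE against ATT turned to 0.0754 with library size alone, 0.0788 with FPKM and 0.193 without the trend, and within single cells RE against ATT turned to −0.179 without it. For RE against ATT with 1 library left out, ATP5O ran from −1.09 to 0.140, UQCRC2 from −0.938 to 0.0193 and the median of matrix genes from −0.0619 to 0.998. The median of ribosomal proteins in clusters ran from −0.0147 to 0.449.

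The other values were those of named genes, of examples from lists that passed, and of those lists. Most were chosen for large changes in the main fit, so their stability says little about other genes. Under another normalization, filter or model, those with a test mostly kept their direction and side of the threshold. They numbered 358 of 362 with DESeq2 size factors in edgeR and 350 of 362 with limma-voom. With no filter or without the covariate 337 of 362 did. With the DESeq2 Wald test 313 of 362 did, where 36 passed that had not and 13 no longer did. Without ATT-SC 352 of 433 did, and 68 passed that had not. Without DE-SC 58 of 433 no longer passed. With the length and GC trend removed, 514 of 587 values kept both, or stayed within their interval where there was no test, and with library size alone 457 of 516 did. Ratios of single libraries depended more on the scale. With FPKM 140 of 154 kept their sign but left their 95% interval, 13 stayed within it and 1 turned, and with a prior count of 5, 35 of 154 left it.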

Other observations

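The single genes in the next 2 paragraphs, and the test for carry-over, were chosen after their values were seen, and the count over splits of the libraries was planned.

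NLRC5, the transactivator of class I genes, rose by 4.62 ± 0.42 (log2 ± SE) in detached cells and by 4.56 ± 0.42 in reattached cells against attached cells (edgeR adjusted p = 0.00299 and 0.0250), from 0.159 and 0.104 CPM in ATT-SC and ATT-CL. HLA-B rose by 2.51 ± 0.25 and 2.44 ± 0.25, HLA-C by 1.94 ± 0.24 and 1.89 ± 0.24, and the peptide transporter TAP1 by 1.93 ± 0.32 and 2.58 ± 0.33. HLA-A rose by 1.36 ± 0.24 in detached cells, and its 1.12 ± 0.24 in reattached cells did not pass (edgeR adjusted p = 0.166). B2M, the light chain of class I molecules, did not pass in either, at 0.23 ± 0.35 and 1.07 ± 0.36.

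In detached cells, CYP1A1 rose by 4.78 ± 0.52, CYP1B1 by 2.98 ± 0.36, AHRR, a repressor of the aryl hydrocarbon receptor, by 2.53 ± 0.36 and TIPARP by 1.09 ± 0.25. In reattached cells CYP1A1 rose by 3.81 ± 0.50 against attached cells, while CYP1B1 at 2.33 ± 0.35 did not pass (edgeR adjusted p = 0.0548).

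Part of the response to suspension may persist after reattachment, as a hypothesis. It was tested across genes on pairs of ratios that share no library. DE-SC against ATT-SC correlated with RE-CL against ATT-CL at 0.387 (Pearson, 16790 genes), and DE-CL against ATT-CL with RE-SC against ATT-SC at 0.201. The Spearman correlations were 0.398 and 0.137. Without the trend with length and GC content the Pearson correlations were 0.390 and 0.271. RE against ATT itself correlated between single cells and clusters at only 0.215 (Pearson) and 0.077 (Spearman), which limits what these values can show. Genes are not independent replicates, and time in culture, which no label gives, was not tested.

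For clusters against single cells over the 3 states, the count of 0 genes was met or passed in 10 of the 10 splits of the 6 libraries into 3 and 3, and the highest other split gave 3614. With a count of 0 every split meets it, so this says nothing about chance, and so few splits cannot give a share under 0.05. The splits with 3614 genes are those that keep both detached libraries together and both reattached libraries together, so both are the same contrast of ATT-SC with ATT-CL. This points to a structure of the samples, but its error comes from the detached and reattached pairs alone, so it is no test of the attached cells. Among genes with at least 1000 reads in some library, ATT-SC lay at least 8-fold above all 5 others for 1 gene and below them for 7, and ATT-CL below for 2, with 0 for the 4 other libraries.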
